A study of Mus musculus with 34 samples.

How the data were processed

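Chromatin accessibility was profiled by paired-end ATAC-seq, in which the Tn5 transposase cuts and tags open DNA, in male germ cells of adult mice. Per the labels, 34 libraries fall into 12 groups, 4 stages in 3 genetic backgrounds. The stages are a meiotic fraction (MS), round spermatids (RS), elongating and condensing spermatids (ES) and mature sperm from the cauda epididymis (Sp). The backgrounds are SV129 mice, C57BL6 mice with intact Gcn5 (WT), and C57BL6 mice in which floxed Gcn5 alleles were removed by a Cre recombinase driven from Stra8, a gene switched on at the start of meiosis (cKO). SV129 has 4 libraries at each of MS, RS and ES, from 2 biological replicates with 2 technical repeats each, and 6 at Sp. WT and cKO have 2 libraries in every group.

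Per the labels' protocols, testis cells were separated by velocity sedimentation, fractions of at least 85% purity were pooled, and each SV129 collection used 11 mice. Sperm were treated with a somatic cell lysis buffer. Reactions held 100000 meiotic cells or sperm, or 200000 spermatids, with Tn5 at 2.5 or 5 units in parallel and 12 PCR cycles. The submitters' processing notes name STAR 2.5.2a and MACS2 2.1.0.20140616, without giving their role, and the mouse build GRCm38 (mm10).

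For each group the authors deposited 1 list of nucleosome calls and 1 list of subnucleosome peaks, 24 lists in all, with no values per library. How fragments were divided into classes, how calls were made and how replicates were combined is not given in the sources used here. Every nucleosome call is 150 bp wide. The calls often overlap: in the 12 lists, 43.0% to 59.3% of neighbouring calls had centres under 150 bp apart, and 20 to 29 bp was the most common 10 bp class of distances. The distances were therefore not read as linker lengths. The score column that the authors deposited with the nucleosome calls runs from 0 to below 0.005, has many ties, and neither its meaning nor its direction is stated, so no call was ranked by it. In the subnucleosome lists of WT and cKO the deposited score of each peak is 3.01 or more on an unstated scale. Peak names in these lists carry the number of 1 library only (replicate 1 at MS, RS and ES and replicate 2 at Sp) and skip numbers, so each list holds part of a longer numbered set, from 29.7% to 75.8% of the highest number. The SV129 subnucleosome lists have no names and a deposited score of 0 throughout. Read depth is unknown, and longer lists can come from deeper libraries.

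With 1 list per group there is no replicate error, and no test between conditions was made. The difference between SV129 and WT, both with intact Gcn5, served as a yardstick for the difference between cKO and WT. It mixes strain, depth and library number. Shares are given with Wilson 95% confidence intervals, which cover counting error only and treat calls as independent, although calls overlap. Ratios of list lengths, covered length and gene counts have no error. An interval on a fold at gene ends is the Wilson interval of the share, that on the X to autosome ratio takes the X counts as Poisson, that on a median score comes from 1000 bootstrap draws, and that on the difference between autosomes and X covers the X share only.

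The gene table used has the positions of 21887 protein-coding genes on chromosomes 1 to 19, X and Y in the same build, without strand, exons or transcripts. Gene ends therefore replaced the planned transcription start sites: a gene was called occupied when a call overlapped the 500 bp on either side of either annotated end. The class of gene end thus mixes promoters with 3' ends, and call centres were divided into gene end, remaining gene body and outside genes. Neighbouring genes can share a call. CpG and GC content was not analysed here, because no genome sequence was used, and random gene lists were not matched on CpG density. Chromosome lengths were taken as the largest coordinate in any list or gene.

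Overlap between lists was counted from 1 bp on, and set beside the mean of 100 circular shifts of the query within each chromosome. The 16 gene lists were fixed before the data were examined, as were the comparisons. Not every name was found in the gene table, and for testis histone variants only 15 of 24 were. For each list, the number of occupied genes, and its difference between cKO and WT, was placed among 10000 random lists of the same size drawn from all genes. A list stood apart below percentile 2.5 or above percentile 97.5. This describes the lists and tests no condition. A list with many occupied genes in WT has more to lose. The number of genes lost in cKO was therefore also placed among random draws from the genes occupied in WT. This was chosen after the main results were seen and before its own values were. The same draws were not made for SV129 against WT, so percentiles among them lack the yardstick between intact lists. Densities around ends used 50 bp bins to 1000 bp, the centre being the 100 bp on either side and the flanks 500 to 1000 bp away.

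Genes were named by a rule set in advance for each stage and class. Kat2a, Prm1, Prm2, Tnp1, Tnp2, Actb and Gapdh were always taken. Each gene list gave up to 3 genes whose occupancy in cKO differed from both WT and SV129, ranked by the change in covered bp within 1000 bp of the ends. The 5 largest gains and 5 largest losses followed, to at most 30 genes. For genes named below, values in bp are the length covered by calls within 1000 bp of either end.

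The code was tested on simulated lists. It counted 1501 overlapping intervals, as did a direct comparison of all pairs, where 1500 had been planted, and it recovered 2000 of 2000 genes with a planted peak. Of 500 random gene lists, 31 fell outside the percentile limits. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives covered the comparator, window, overlap rule, merging of calls, thinning of lists to equal length, autosomes only and a stricter score.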

Results

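The data were 12 lists of nucleosome calls and 12 lists of subnucleosome peaks, 1 of each per stage and background, of mouse male germ cells from meiosis to mature sperm. In this period most histones are replaced by transition proteins and then protamines. The series asks how Gcn5, a histone acetyltransferase encoded by Kat2a, bears on nucleosome changes then. No list has a replicate, so every difference below is between single lists, and its size is set beside that between the SV129 and WT lists, both with intact Gcn5. The depth of the libraries is unknown.

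The first comparison followed the stages in mice with intact Gcn5. Subnucleosome peaks, which mark open sites free of nucleosomes, were numerous at MS and RS, nearly absent at ES, and present again in sperm. SV129 had 33060 peaks at MS, 29243 at RS, 787 at ES and 10715 in sperm, and WT had 35822, 56480, 562 and 3024. Nucleosome calls took another course, with 199111, 230591 and 480320 calls in SV129 at MS, RS and ES, then 13615 in sperm. In WT they numbered 329678, 253621, 591189 and 8628. Between ES and sperm the nucleosome list shortened 35.3 times in SV129 and 68.5 times in WT, to 1.17 Mb and 0.77 Mb of covered sequence.

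**Figure D1:**
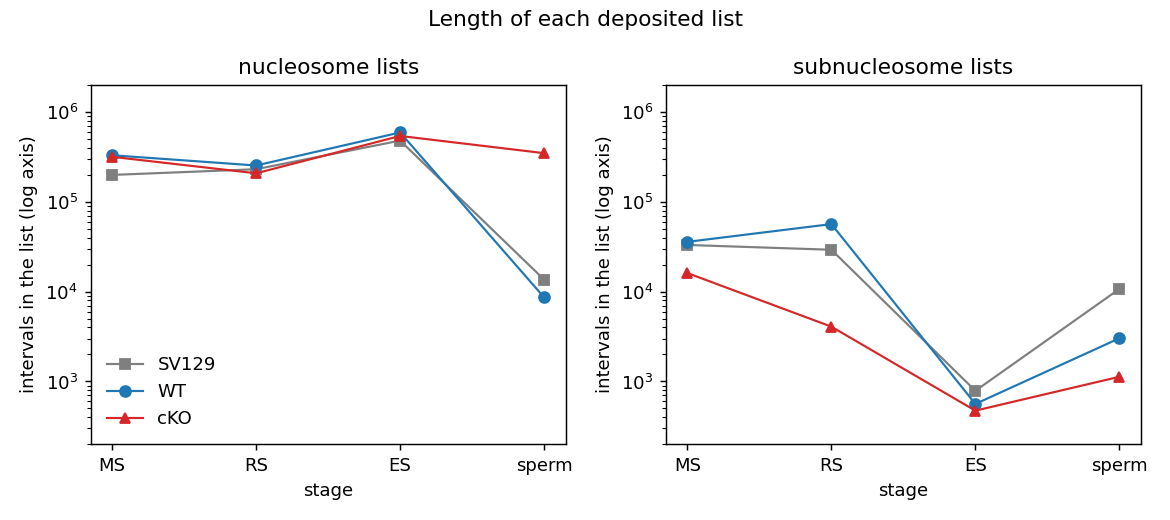
Number of intervals in each deposited list on a log axis against stage, for nucleosome calls (left) and subnucleosome peaks (right); each point is 1 list and colour and marker give the background. The cKO sperm nucleosome list, with 347951 calls, lies far above the WT and SV129 sperm lists with 8628 and 13615.

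Gene ends held far more nucleosome calls than their share of sequence at MS and RS, and much less so at ES, although most calls lay elsewhere at every stage. In SV129, 31.4% of nucleosome call centres at MS lay within 500 bp of a gene end (31.2% to 31.6%), 20.6 times the share of such sequence, against 3.51% at ES (3.45% to 3.56%), 2.31 times. WT went from 23.2% to 2.72%. In sperm 21.8% of calls in SV129 and 20.7% in WT were at ends, and 52.3% and 49.7% were outside genes. Protein-coding genes with a nucleosome call at an end numbered 10880 at MS, 10610 at RS, 8576 at ES and 1486 in sperm of SV129, and 12546, 9958, 7803 and 1012 in WT. For subnucleosome peaks the numbers were 9839, 8772, 19 and 4641 in SV129 and 10407, 10177, 10 and 1752 in WT. Most genes with a sperm peak had one in the meiotic fraction too, 4286 of 4641 in SV129 (92.4%) and 1693 of 1752 in WT (96.6%), where independent placement would give 2086 and 833. At MS and RS subnucleosome peaks were densest around the end itself and nucleosome calls on its gene side. In SV129 at MS the densest bin was centred 25 bp outside the gene for peaks and 125 bp inside it for nucleosome calls.

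Genes of meiosis, of basic cell function and of chromatin regulation had occupied ends more often than random lists in the meiotic fraction, and lineage genes less often. In SV129, 41 of 48 meiotic genes, 43 of 50 housekeeping genes and 25 of 27 subunits of the SAGA and ATAC complexes, which contain Gcn5, had a nucleosome call at an end at MS. All 3 lists lay above the upper percentile limit in both intact backgrounds, in both classes. So did the 33 other chromatin regulators of spermiogenesis, with 27 genes. Of 89 developmental transcription factors 26 had one, and of 1465 olfactory and vomeronasal receptors 38, both below the lower limit. WT had a call at 50 of those transcription factors, within the limits.

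At RS, the 60 spermatid genes, which include acrosome, flagellum and sperm metabolism genes, had subnucleosome peaks at 46 genes in SV129 and 52 in WT, both above the limit. WT fell to percentile 19.5 after thinning to the length of the cKO list, a random draw of 4075 of its 56480 peaks. The 5 protamine and transition protein genes had peaks at 5 and 4. Peaks covered 304 bp near Tnp1 in SV129 and 438 bp in WT, and 158 and 187 bp near Prm1. At MS only 1 of these genes had a peak in either background, Tnp1, with 88 and 116 bp. In sperm, peaks were at 22 housekeeping genes in SV129 and 12 in WT, both above the limit. They were at 14 SAGA and ATAC genes in SV129, above the limit, and 5 in WT, within it, and at 8 and 3 of 60 spermatid genes. No protamine or transition protein gene had an interval of either class at an end in SV129 or WT sperm.

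**Figure D2:**
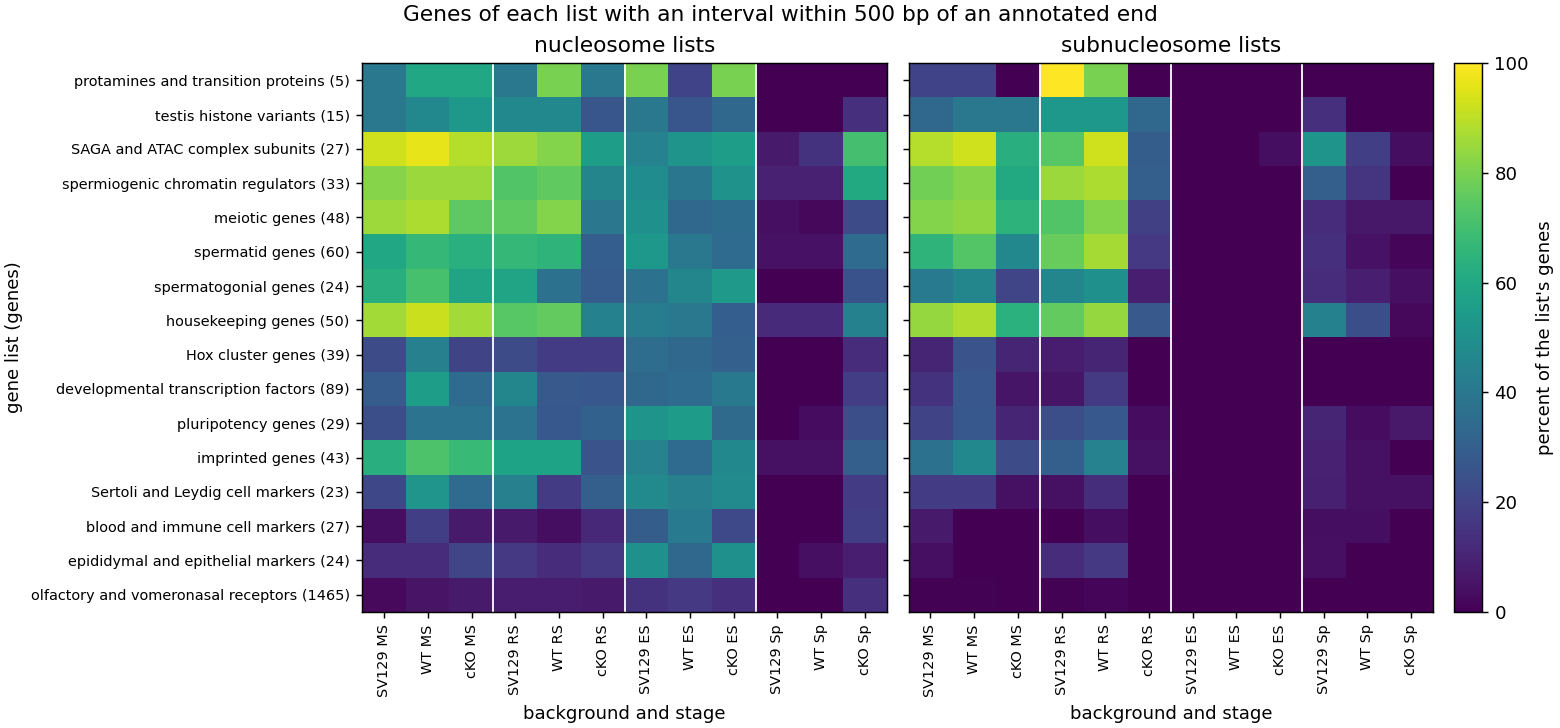
Percent of the genes of each fixed list (rows, number of genes in brackets) that had an interval within 500 bp of an annotated end, in the nucleosome (left) and subnucleosome lists (right) of each background and stage (columns). In WT, 39 of 48 meiotic genes and 52 of 60 spermatid genes had subnucleosome peaks at RS, against 9 and 10 in cKO.

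The sex chromosomes, which are silenced during male meiosis, were compared with autosomes. Calls on X were scarce at RS in every background. The number of nucleosome calls per Mb on X, divided by that on autosomes, was 0.242 in SV129, 0.415 in WT and 0.284 in cKO at MS. At RS it was 0.0193, 0.0295 and 0.0765. For subnucleosome peaks it was 0.425, 0.377 and 0.375 at MS and 0.113, 0.0863 and 0.0499 at RS, the last resting on 14 peaks on X. At ES the subnucleosome ratio was 0.271, 0.401 and 0.323, from 13, 13 and 9 peaks on X. Y, which had a ratio of at most 0.0553 in intact lists at MS and RS, reached 0.744, 0.928 and 0.878, from 19, 16 and 13 peaks. Of the peaks in these short lists 8.01%, 11.7% and 10.6% lay off the numbered chromosomes, X and Y, against at most 0.393% at MS and RS. Nucleosome calls, far more numerous at ES, had ratios of 0.0518, 0.17 and 0.118 on X and 0.0126, 0.0377 and 0.0248 on Y. Sperm had nucleosome ratios of 0.288, 0.114 and 0.22. The RS to MS ratio for nucleosome calls was 0.08 in SV129, 0.071 in WT and 0.269 in cKO.

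**Figure D3:**
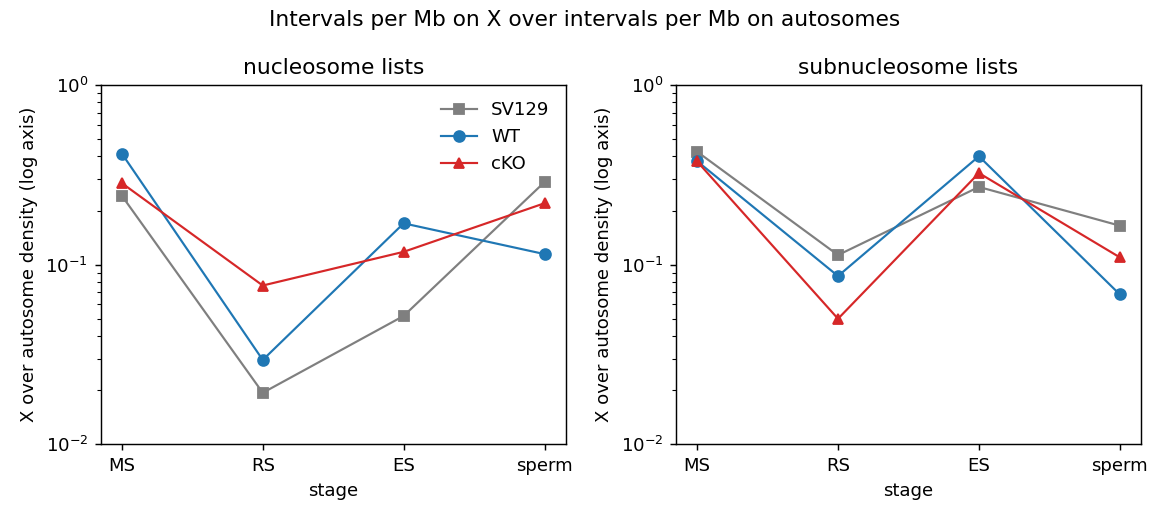
Intervals per Mb on the X chromosome over intervals per Mb on autosomes, on a log axis, against stage for nucleosome (left) and subnucleosome lists (right); each point is 1 list, coloured by background. The nucleosome ratio at RS was 0.0193 in SV129, 0.0295 in WT and 0.0765 in cKO, below that of MS in each.

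The remaining comparisons asked what differed when Gcn5 was removed. Kat2a itself (chromosome 11, 100704746 to 100712485) gave no check of the labels. The gene had 5 nucleosome calls in both WT and cKO at MS and none in SV129. At RS it had 4 calls in WT and none in cKO or SV129, and at ES 5 in SV129, 3 in WT and none in cKO. Subnucleosome peaks were at its upper end in all 3 MS lists. Which part of the gene was floxed is not given in the sources used here, and the lists are too sparse there to show a deletion.

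In the meiotic fraction the cKO subnucleosome list held fewer peaks, and the nucleosome lists of cKO and WT were of similar length. Subnucleosome peaks numbered 16087, 0.449 times WT and 0.487 times SV129, while SV129 had 0.923 times WT. Of the cKO peaks 96.5% overlapped a WT peak (96.2% to 96.8%), and 42.0% of WT peaks overlapped a cKO peak, against 71.1% for SV129. Genes with a peak at an end fell from 10407 to 7242, of which 7199 were shared. Among equal numbers of randomly drawn peaks cKO had 1.4 times as many such genes as WT, as cKO peaks lay at ends more often (42.5% against 28.8%). Near Wdr5 and Trrap, subunits of ATAC and SAGA, 760 and 740 bp were covered in WT, 651 and 241 bp in SV129, and none in cKO. The same held for Sirt1, a histone deacetylase (523, 313 and 0 bp), for Odf2 and Tekt2, structural genes of the sperm tail (945, 519 and 0 bp; 587, 301 and 0 bp), and for the DNA methyltransferase Dnmt3b (491, 385 and 0 bp). Of the genes occupied in WT, 30.8% lost their peak. Developmental transcription factors lost 19 of 24, percentile 100 among draws from occupied genes, with Six2, Emx2 and Tbx2 among them. SV129, with intact Gcn5, had peaks at only 13 genes of this list. Against all genes, its difference from WT stood at percentile 0.035, and that of cKO at 4.015. Hox cluster genes lost 6 of 10 (percentile 96.6), pluripotency genes 5 of 8 (96.2) and imprinted genes 10 of 20 (96.2), all within the limits. Sertoli and Leydig cell markers lost 3 of 4 (percentile 95.2), also within them. Testis histone variants lost 0 of 6 (percentile 5.45), within the limits as well.

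Nucleosome calls at MS in cKO were 0.961 times WT and 1.59 times SV129. Of cKO calls 33.7% overlapped a WT call, against 69.0% of the fewer SV129 calls. Of WT calls 38.3% overlapped a cKO call and 44.7% an SV129 call. Genes with a call at an end numbered 11185 in cKO and 12546 in WT, with 9965 shared. Call centres at gene ends were 15.1% of the cKO list, 23.2% of WT and 31.4% of SV129. Per 1000 ends and 50 bp, the central density was 64.0 call centres in cKO, 112 in WT and 106 in SV129. Hox cluster genes went from 17 occupied in WT to 8 in cKO (percentile 0.715), including loss at Hoxc6, Hoxc8 and Hoxc13, but SV129 had 9 as well. Of the markers of other cell types, those of Sertoli and Leydig cells had 12 occupied in WT, 8 in cKO and 5 in SV129, those of blood and immune cells 5, 2 and 1, and epididymal and epithelial markers 3, 5 and 3, all differences within the limits. The blood and immune markers lost all 5 genes occupied in WT, above the limit among draws from such genes (percentile 99.975), and gained 2 others. The net count of receptor genes went the other way, with 77 in WT, 104 in cKO and 38 in SV129. They gained 84 genes but lost 57 of the 77, more than draws from genes occupied in WT (percentile 100).

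The subnucleosome list of round spermatids was far shorter in cKO than in either intact background, though a single poor cKO library may account for this. The cKO list held 4075 subnucleosome peaks, 0.0721 times WT and 0.139 times SV129, where SV129 had 0.518 times WT. Nearly every cKO peak was a WT peak (99.8%, 99.6% to 99.9%), and 7.03% of WT and 13.4% of SV129 peaks overlapped a cKO peak. All 2446 genes with a cKO peak at an end were among the 10177 of WT, a ratio of 0.24, or 0.141 with the upper 50% of each list by score. Among equal numbers of randomly drawn peaks the ratio turned to 2.8, as cKO peaks lay at ends more often (51.5% against 18.2%). Near Tnp1 (chromosome 1, 73015074 to 73015899), Prm1 (chromosome 16, 10796332 to 10796823) and Prm2 (chromosome 16, 10791377 to 10792105), where WT had 438, 187 and 224 bp and SV129 304, 158 and 183 bp, cKO had none. All 4 protamine and transition protein genes occupied in WT lost their peak, within the limits among draws from genes occupied in WT (percentile 83). Peaks were likewise absent in cKO near Sycp1 of the synaptonemal complex (782 bp in WT, 412 bp in SV129), the sperm kinase gene Tssk6 (710 and 418 bp), Sirt1 (850 and 258 bp) and the RNA helicase gene Ddx5 (1286 and 721 bp). Dazl, a germ cell RNA-binding protein gene, kept 81 bp of 776 bp.

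Peaks with high scores and peaks at gene ends were retained more often than others. With WT peaks in 10 parts of about equal size by score, 0.0355% of the lowest part overlapped a cKO peak, and 43.4% of the highest. Of WT peaks at gene ends 19.7% did, of others 4.03%. Most lists of germ cell genes lost peaks at the general rate. Of all genes occupied in WT 76.0% lost their peak, of spermatid genes 42 of 52, of meiotic genes 30 of 39, of spermatogonial genes 10 of 12, of housekeeping genes 28 of 42, of SAGA and ATAC genes 17 of 25 and of other chromatin regulators 19 of 29. Except for the spermatogonial genes, these lists fell below percentile 2.5 against all genes, but the direction turned after thinning of both lists to equal length. After thinning, chromatin regulators at 99.5, housekeeping genes at 99.1 and SAGA and ATAC genes at 97.9 passed the opposite limit, and spermatid and meiotic genes stood at 95.035 and 73.5. Thinning drew WT peaks at random, and these lay at ends less often than cKO peaks (18.2% against 51.5%). The turn can follow from this alone, so it does not bear on which genes lost peaks. All 6 lay within the limits among draws from genes occupied in WT. Developmental transcription factors lost 15 of 15 and the receptors 28 of 28, more than such draws (percentiles 99.2 and 100). SV129, with intact Gcn5, had peaks at only 5 and 11 genes of these lists. Against all genes, both lists lost fewer than random lists (percentiles 99.985 and 100 of the difference). Testis histone variants lost 3 of 8, fewer than draws from genes occupied in WT (percentile 1.4). H1f7, Hils1, H2ac1, H2bc1 and H2ax kept a peak, and H1f6, H2al2a and H3f3a lost it. H2ac1 and H2bc1 are neighbours and can share a peak, and H2ax and H3f3a are not specific to the testis.

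**Figure D4:**
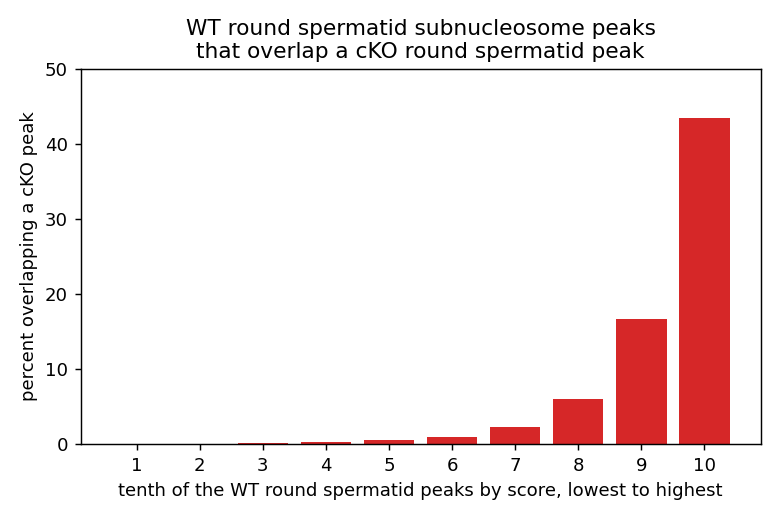
Percent of WT round spermatid subnucleosome peaks that overlapped a cKO round spermatid peak, in 10 parts of the WT list from the lowest to the highest score; bars are shares of 5454 to 5893 peaks. The share was 0.0355% in the lowest part and 43.4% in the highest.

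Nucleosome calls at RS were fewer at gene ends in cKO than in both intact backgrounds. The cKO list held 207681 calls, 0.819 times WT, where SV129 had 0.909 times WT, but 7.47% of cKO call centres were at gene ends (7.36% to 7.58%) against 17.9% in WT and 19.1% in SV129. Genes with a call at an end numbered 6630 in cKO, 9958 in WT and 10610 in SV129. Per 1000 ends and 50 bp, the central density was 18.9 call centres in cKO, 93.0 in WT and 76.6 in SV129. Calls were absent in cKO near Tnp1 (485 bp in WT, 170 bp in SV129), the spermatid linker histone genes Hils1 (340 and 290 bp) and H1f6 (300 and 340 bp), the sperm glycolysis gene Pgk2 (580 and 470 bp), Sycp3 (597 and 630 bp) and Foxo1 (855 and 761 bp), and present only in cKO near Sohlh1 (326 bp). Near Prm2 and Tnp2 calls covered 300 and 150 bp in WT, 340 and 327 bp in cKO and 0 and 170 bp in SV129. Of genes occupied in WT 49.6% lost their call, of spermatid genes 25 of 39 (percentile 96.4) and of meiotic genes 20 of 39 (percentile 57.4). The most common score differed between the lists, at 0.000975 in cKO and 0.00439 in WT. Calls at each list's own most common score were 66.7% of the cKO list and 17.4% of the WT list. Without them the cKO list was 0.33 times as long as WT, and its calls lay at gene ends 9.24 times as often as the share of such sequence, against 13.9 times in WT.

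In elongating spermatids the 3 backgrounds differed little in the number of calls, and few nucleosome calls overlapped between any 2 lists, the intact ones included. Nucleosome calls in cKO were 0.915 times WT, and SV129 had 0.812 times WT. Of cKO calls 7.39% overlapped WT calls, 2.02 times the level of shifted positions, and of WT calls 7.35% overlapped SV129 calls, 2.11 times. WT calls overlapped SV129 calls 41.8 times the shifted level at MS and 25.9 times at RS. Whether ES calls differ in place between backgrounds or repeat poorly between lists cannot be told. Genes with a call at an end numbered 8211 in cKO, 7803 in WT and 8576 in SV129. The protamine and transition protein genes had 4 occupied of 5 in cKO, 1 in WT and 4 in SV129. Subnucleosome peaks were few, with 473 in cKO, 562 in WT and 787 in SV129, and 82.7% of cKO peaks overlapped a WT peak (78.9% to 86.0%). Genes with a peak at an end were 21, 10 and 19, and the ratio of cKO to WT was 1.00 in the upper 50% of each list by score. The highest peak number in cKO was 1.46 times that in WT. Near Cycs, a cytochrome c gene, Ankrd50, Zbtb20 and Rab30, cKO had 174, 171, 144 and 95 bp covered and both others none.

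In sperm the classes moved apart. The cKO nucleosome list held 347951 calls, 40.3 times WT and 25.6 times SV129, where SV129 had 1.58 times WT, and it covered 29.6 Mb against 0.77 Mb in WT. Without the calls at each list's own most common score, 70.1% of the cKO list and 35.5% of WT, it was 18.7 times as long. That score was 0.00195 in cKO and 0.000975 in WT, so the calls left out were not alike. Those left out lay at gene ends 2.23 times as often as the share of such sequence in cKO and 13.7 times in WT. Genes with a nucleosome call at an end numbered 7712 in cKO (35.2%, 34.6% to 35.9%), 1012 in WT and 1486 in SV129. Among equal numbers of randomly drawn calls, cKO had 0.559 times as many such genes as WT. Of the WT calls 49.6% overlapped a cKO call, and of the cKO calls 1.29% overlapped a WT call, 26.1 times the shifted level. Call centres at gene ends were 5.57% of the cKO list, 20.7% of WT and 21.8% of SV129. Without the most common score, calls lay there 7.09 times as often as the share of such sequence in cKO and 13.5 times in WT. SAGA and ATAC genes had 19 occupied of 27 in cKO, 4 in WT and 2 in SV129 (percentile of the difference 99.5), with Trrap (529 bp), Yeats2 (387 bp) and Wdr5 (327 bp) among the new ones. Other chromatin regulators had 20 of 33, 3 and 3 (percentile 99.2), with Ep300, an acetyltransferase gene (675 bp), and Sirt1 (497 bp). Housekeeping genes had 22, 6 and 6, spermatid genes 21, 3 and 3, and meiotic genes 11, 1 and 2, all within the limits. Hox genes with 5 occupied of 39, developmental transcription factors with 16 of 89, epididymal and epithelial markers with 2 of 24 and receptors with 197 of 1465 gained less than random lists. After thinning to equal length none of these 6 lists stayed past its limit, with SAGA and ATAC genes at percentile 14.1, other chromatin regulators at 6.64 and Hox genes at 87.0, while the receptors crossed to 99.99, past the opposite limit. No protamine or transition protein gene was occupied in cKO.

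Subnucleosome peaks in cKO sperm numbered 1127, 0.373 times WT and 0.105 times SV129, while SV129 had 3.54 times WT, a gap between intact lists larger than that between cKO and WT. By the highest peak number the cKO to WT ratio was 0.204. Genes with a peak at an end numbered 732 in cKO, 0.418 times WT, or 0.277 times in the upper 50% of each list by score. Among equal numbers of randomly drawn peaks it was 1.08 times. Of cKO peaks 50.2% overlapped WT peaks (47.2% to 53.2%) and 93.2% overlapped SV129 peaks. Housekeeping genes had 1 occupied of 50 in cKO, 12 in WT and 22 in SV129, and all 12 of WT were lost (percentile 96.5 among occupied genes). Peaks were absent in cKO near Canx and Rps18 (240 and 204 bp in WT), Usp22, the SAGA deubiquitinase gene (262 bp), Ep400 (402 bp) and the sperm glycolysis gene Gapdhs (149 bp). Peaks were present in cKO and SV129 and absent in WT near Pdcd10 and its neighbour Serpini1 (534 and 450 bp) and near Papss1 (308 and 233 bp).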

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

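The tests of X copy number, of list selection, of depth and of spermatids among sperm were chosen after their own values were seen, and those of score ranks in round spermatids, of random placement and of matched X peaks after the patterns were seen but before the values of the tests were.

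The cKO to WT ratio of nucleosome calls was above 1 in sperm, at 40.3, and below 1 at the other stages, 0.961 at MS, 0.819 at RS and 0.915 at ES; this difference between stages was not tested, and against SV129 the ratio was above 1 at MS (1.59) and ES (1.13) as well. Uniform random placement of every call at the most common score is argued against. Calls at the most common score were 70.1% of the cKO sperm list. They lay at gene ends 2.23 times as often as the share of such sequence (2.18 to 2.28). A set of mostly random calls with some at gene ends would also give this fold, so random placement of most of them stays open. Whether calls at this score are weakly supported is unknown, as the direction of the score is not stated. The fold is over chromosome length alone, so uneven placement for technical reasons was not tested. Deeper cKO sperm libraries stay open: the subnucleosome list was shorter in cKO, at 0.373 times WT, but its peak names carry 1 library only. The nucleosome list may hold both libraries, and how replicates were combined is not given. Elongating spermatids among the cKO sperm cannot be told apart from retained nucleosomes in sperm, because cKO sperm calls overlapped cKO ES calls 1.89 times as often as shifted positions, less than cKO MS (3.7) or RS calls (3.2), but the intact ES lists overlapped each other only 2.11 times. Nucleosomes retained through loss of Gcn5, the difference the design names, remain open and untested.

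The cKO list of round spermatids held 0.0721 times as many subnucleosome peaks as WT. A stricter selection of cKO peaks by the authors is argued against by the peak numbers, whose highest value in cKO was 0.0614 times that in WT. A general loss of sensitivity that drops the weakest peaks first is consistent with the scores, since the WT peaks that overlapped a cKO peak had a median score at percentile 92.8 of the WT list (92.4 to 93.0). The test could have come out the other way, but a shallower or noisier library and weaker opening of every site by loss of Gcn5 would both give it, and nothing here separates them. The peak names carry 1 library, so a single poor cKO library may account for the list.

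Calls on X were scarce in round spermatids. A lower number of X copies is argued against: X makes up the same share of chromosomes before and after the meiotic divisions, yet the X to autosome density in WT at RS was 0.071 times that at MS (0.065 to 0.0776). Weaker X peaks already at MS are argued against as well, since WT MS peaks at matched scores were found again at RS 33.3 percentage points more often on autosomes than on X (30.2 to 36.2), with 31.6% of the 909 X peaks found again. What stays open is the silencing of the sex chromosomes that continues after meiosis, as a hypothesis, and a mapping filter on X that differed between stages, which was not tested.

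Sequence outside the numbered chromosomes, X and Y was left out of the gene comparisons. The unplaced scaffold JH584304 alone had 1274 nucleosome calls in WT sperm, 14.8% of the list, 1040 in SV129 sperm, 7.64%, and 1097 in cKO sperm, 0.315%.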

How the results depend on the processing

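No paired analysis was possible because each group has 1 list and the files hold no values per replicate, and leaving out replicates was not possible for the same reason. Calls without the most common score, the highest peak number, gene-length matching and the restriction to numbered chromosomes, X and Y were chosen after the results were seen. Not run were start sites of any transcript, genes ranked by CpG and windows matched on GC, which need references not used here. A stricter score was not applied to nucleosome lists, whose score has no stated direction, or to SV129 subnucleosome lists, whose scores are all 0.

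With SV129 in place of WT, the ratio of nucleosome calls in cKO was 1.59 at MS, 1.13 at ES and 25.6 in sperm, and that of covered length 1.73 at MS and 25.3 in sperm. For subnucleosome peaks it was 0.139 at RS and 0.105 in sperm, and for covered length 0.111 and 0.112. The ratio of genes with a subnucleosome peak was 1.11 at ES and 0.158 in sperm. Without each list's own most common score the ratio of nucleosome calls was 0.33 at RS and 18.7 in sperm. That score differed between cKO and WT, so these ratios do not compare like with like. By highest peak number the subnucleosome ratio was 1.46 at ES and 0.204 in sperm.

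When at least 50% of the call had to overlap WT, the share of cKO nucleosome calls was 30.2%, 11.3%, 5.2% and 1.15% at MS, RS, ES and Sp, and of subnucleosome peaks 96.1% at MS and 44.4% in sperm. With both lists thinned to the shorter, it was 33.5%, 12.5%, 7.09% and 1.25% for nucleosome calls and 43.7%, 6.8%, 71.4% and 18.9% for subnucleosome peaks. In the upper 50% by score the subnucleosome share was 95.1% at MS, 98.9% at RS and 88.8% at ES, and the ratio of genes with a peak 0.141 at RS, 1.00 at ES and 0.277 in sperm.

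After thinning of lists to the shortest, the ratio of genes with an interval turned to 0.559 for nucleosome calls in sperm, and to 1.4 at MS, 2.8 at RS and 1.08 in sperm for subnucleosome peaks. The cKO to WT ratio of the share at gene ends, counting any overlap with an end, was 0.428 for nucleosome calls at RS and 1.43 and 2.72 for subnucleosome peaks at MS and RS. With ends of 1000 bp it was 0.483, 1.2 and 0.319 for nucleosome calls at RS, ES and Sp, and 1.4 and 2.55 for subnucleosome peaks at MS and RS. By covered bp, the RS to MS ratio of X density was 0.0679 in SV129, 0.0614 in WT and 0.23 in cKO for nucleosome calls, and 0.217 in SV129 for subnucleosome peaks.

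Thinning drew intervals at random, whatever their score, so a list with a larger share of intervals at gene ends gained from it. A crossing after thinning therefore does not show which genes lost or gained intervals. Gene list percentiles of the difference between cKO and WT crossed to the other side after thinning. For nucleosome calls in sperm they were 14.1 for SAGA and ATAC complex subunits, 6.64 for spermiogenic chromatin regulators, 87.0 for Hox cluster genes, 77.1 for developmental transcription factors and 99.99 for olfactory and vomeronasal receptors. For subnucleosome peaks at MS they were 98.2 for SAGA and ATAC complex subunits, 97.495 for spermatid genes, 15.9 for blood and immune cell markers, 16.7 for epididymal and epithelial markers and 0 for olfactory and vomeronasal receptors. For subnucleosome peaks at RS they were 97.9 for SAGA and ATAC complex subunits, 99.5 for spermiogenic chromatin regulators, 73.5 for meiotic genes, 95.035 for spermatid genes, 99.1 for housekeeping genes, 9.79 for Hox cluster genes, 2.6 for developmental transcription factors, 5.84 for Sertoli and Leydig cell markers, 15.0 for blood and immune cell markers, 16.6 for epididymal and epithelial markers and 0 for olfactory and vomeronasal receptors. For subnucleosome peaks in sperm olfactory and vomeronasal receptors had 34.2. Thinned occupancy gave 21.0 for spermiogenic chromatin regulators and 55.4 for Hox cluster genes in the cKO_Sp nucleosome list, and 19.5 for spermatid genes, 78.2 for pluripotency genes and 58.3 for Sertoli and Leydig cell markers in the WT_RS subnucleosome list. With SV129 as comparator, nucleosome differences gave 84.1 and 42.9 for developmental transcription factors at MS and RS and 65.4 for olfactory and vomeronasal receptors at ES.

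Of the remaining single-list percentiles under an alternative, 1430 kept their call and 85 fell back within the limits. Another 55 moved from within the limits to outside them, and their side was not compared with the first value. Hox cluster genes in subnucleosome lists at MS, for example, went from 41.6 to 99.3 with SV129 as comparator.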

Other observations

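The counts by place and score were chosen after the results were seen, and the test of proportional loss after the main results were seen but before its own value was.

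Receptor genes and markers of other cell types had nucleosome calls at more ends in elongating spermatids than in the meiotic fraction, while all genes together had fewer. The ES lists were longer, and their calls lay at gene ends 2.31, 1.79 and 2.21 times as often as the share of such sequence in SV129, WT and cKO. At MS it was 20.6, 15.3 and 9.90 times. A rise at ends with few calls at MS can follow from this alone, and the difference between stages was not tested. Receptor genes had 217 occupied of 1465 at ES in SV129, 243 in WT and 202 in cKO, against 38, 77 and 104 at MS. They stayed below the share of all genes occupied at ES, which was 39.2%, 35.7% and 37.5%. Epididymal and epithelial markers had 12, 8 and 12 of 24 at ES and 3, 3 and 5 at MS, and blood and immune markers 8, 11 and 6 of 27 at ES and 1, 5 and 2 at MS. Sertoli and Leydig cell markers had 11, 10 and 11 of 23 at ES and 5, 12 and 8 at MS, so WT did not share the rise. Pluripotency genes had 15, 16 and 10 of 29 at ES, above the upper percentile limit in WT. In subnucleosome lists the markers of other cell types had peaks at few ends: blood and immune markers at 2 or fewer in each list, epididymal and epithelial markers at 4 or fewer, and Sertoli and Leydig markers at 4 or fewer.

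Imprinted genes, expressed from the copy of 1 parent, had nucleosome calls at 27 of 43 in SV129, 31 in WT and 29 in cKO at MS, and subnucleosome peaks at 16, 20 and 10. At RS, nucleosome calls were at 25, 25 and 11 and peaks at 13, 19 and 2. Spermatogonial genes had peaks at 10, 11 and 5 of 24 at MS and 11, 12 and 2 at RS.

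A hypothesis was that gene lists lost peaks in cKO round spermatids in proportion to their peaks in WT. Of the 5 lists that lost more than random lists of all genes, 0 lost more than random draws from genes occupied in WT. For these 5 lists no departure from a proportional loss was seen. Other lists did depart in the same draws at RS. Developmental transcription factors and receptors lost more (percentiles 99.2 and 100), and testis histone variants fewer (1.4). Over all stages and both classes, 38 of 128 differences between cKO and WT lay outside the limits against all genes, and 21 of 128 between SV129 and WT. Among draws from genes occupied in WT, 12 of 99 numbers of genes lost in cKO lay outside the limits.

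Peaks at gene ends were retained more often than other peaks of high score in round spermatids. Among the top 10% of WT peaks by score, 57.4% of the 2401 at gene ends overlapped a cKO peak, and 33.1% of the 3242 elsewhere.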
